A study of Mus musculus with 9 samples.

How the data were processed

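RNA from RF8 mouse ES cells was sequenced as 9 libraries, 1 for each of 3 transfectants (EGFP, Nanog WT, Nanog L122A) in each of 3 cultures. Per the labels the routine culture held 1000 units of LIF per ml and puromycin, the RA culture held 5 µM RA and no LIF, and total RNA was extracted with an RNeasy kit and made into Illumina libraries. The time in each culture is not in the labels. Reads were aligned with TopHat2 2.0.11 to mm9, per the labels; the counting program, its version, the handling of strand and any read filter are not given in the sources used here. The raw count of reads per gene was made by the authors and is not normalized, per the file headers. The FPKM values, normalized per the file headers, were compared with the count divided by feature length and by the file's own total count. In every library 100% of genes above 5 FPKM matched this formula within 1%. The columns for cultures without LIF and with RA are named as in the sample titles, the column name L122 was taken as L122A, and a column name that is in no label was assigned to the culture with LIF by elimination, which the labels do not state.

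The file lists 33495 genes, of which 28692 identifiers matched a symbol in a newer mouse annotation that was used for names alone, and 25920 had a count in any library. Coordinates are those of the file. Counts were analysed with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3, and single libraries and figures with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes with at least 1 CPM in at least 3 of the 9 libraries were tested (13996). Libraries were scaled by trimmed-mean (TMM) factors, from 0.810 (L122A no-LIF) to 1.255 (L122A RA).

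With 1 library per combination, the effects of culture and transfectant were tested in an additive edgeR quasi-likelihood model of both factors (robust, 4 residual degrees of freedom, biological coefficient of variation 0.325), at a Benjamini-Hochberg adjusted p below 0.05. The spread in this model is the departure from additivity, so it includes any interaction. Its p-values ask whether an effect repeats over the levels of the other factor, not over replicate cultures. The SE given is the absolute log2 fold change over the square root of the F statistic, not a separately estimated standard error. Whether the response to a culture differed between Nanog transfectants and EGFP was tested on the means of each class in each culture, with WT and L122A as 2 libraries of the Nanog class (3 residual degrees of freedom, coefficient of variation 0.287). Libraries within 1 culture were compared without a test, as ratios of CPM with exact 95% Poisson intervals, which cover counting error only, and as log2 ratios with a prior count of 2. A gene counted as different at 2-fold or more with at least 5 CPM in the higher library. A count of 0 was given a floor of 3 counts where a list median was recomputed.

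The genes named, the 16 lists, the tests and the first set of alternatives were fixed before the data were examined. Named are Nanog; for each comparison the 5 called genes with the largest increase and the 5 with the largest decrease, among genes with a mean of at least 5 CPM and, outside the differences of responses, 1 direction in all 3 matched pairs; per list the 2 called members with the largest change each way or, where none passed, the member with the smallest p; and, within a culture, list members and the 5 genes with the largest ratio each way that moved at least 2-fold in both Nanog libraries. Some genes that this rule names are not reported here. The lists are naive pluripotency, general pluripotency, formative and primed epiblast, LIF and STAT3 target, Nodal and BMP target, retinoic acid response, anterior Hox, extraembryonic endoderm, mesoderm and primitive streak, neural ectoderm, trophectoderm, cleavage stage, germ cell, fibroblast, cell cycle and p53 target genes, written from general knowledge; 220 of their 225 genes matched the file. They were tested with camera (correlation preset at 0.01, and again estimated) and fry from limma on log2 CPM, with Benjamini-Hochberg adjustment over the lists of a comparison. Single-library list medians were set against 10000 random lists matched on expression. A list of YAP and TEAD targets and one of the 77 ribosomal protein genes were added after the data had been seen.

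Alternatives were RLE factors, no filter, DESeq2, only the libraries of the levels compared, limma on log2 FPKM with a pseudocount of 1, no second factor, and leaving out each library in turn; for single libraries, a prior count of 0.5, a minimum of 1 CPM, and RLE factors. Scaling by total counts and leaving out the 190 ribosomal RNA and 38 mitochondrial genes, sets that share the mitochondrial ribosomal RNA genes, were added after the data had been seen. Tested on simulated data with 200 changed genes, the additive model recovered between 8.96% and 22.4% of 2-fold, between 62.7% and 79.1% of 4-fold and between 87.9% and 95.5% of 16-fold changes, and the interaction model 1.49%, between 20.9% and 26.9%, and between 78.8% and 81.8%. False calls were between 4.38% and 11.0% of calls. Reads shared between near-identical genes (Zscan4 family, ribosomal pseudogenes such as Rpl27-ps2) or overlapping genes cannot be assigned from these counts.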

Results

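The series measured gene expression by RNA sequencing in RF8 mouse embryonic stem (ES) cells transfected with 1 of 3 constructs: enhanced green fluorescent protein (EGFP), wild-type Nanog (WT), or Nanog carrying the L122A change (L122A), which the series title places among mutants of the homeodomain, the DNA-binding domain of this pluripotency transcription factor. Each transfectant was grown in 3 cultures: with leukaemia inhibitory factor (LIF), a cytokine that sustains ES cell self-renewal, at 1000 units per ml; without LIF; and without LIF in the presence of 5 µM retinoic acid (RA), an inducer of differentiation. There was 1 library for each of these combinations, 9 in all, and no combination had a replicate. Libraries are named here by transfectant and culture (EGFP LIF, EGFP no-LIF, EGFP RA, and likewise for WT and L122A). Total gene counts were 28692848, 26922401 and 28714988 in the EGFP LIF, no-LIF and RA libraries, 24778937, 26076780 and 26144980 in the WT libraries, and 24166395, 24386322 and 28421480 in the L122A libraries. Genes for ribosomal RNA held 15.9%, 15.0% and 16.7% of these counts in EGFP, 23.1%, 18.6% and 19.1% in WT, and 20.6%, 22.8% and 15.96% in L122A, in the same order. This share includes mitochondrial ribosomal RNA, at 12.0%, 14.8% and 11.4% in the EGFP, WT and L122A RA libraries. The gene SSU_rRNA_5 held 4.72%, 4.30% and 4.53% in these libraries, and between 7.86% and 11.8% in the others.

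The RA libraries stood apart from the other 6. The first principal component of log2 CPM (counts scaled to library size) held 62.5% of the variance and placed the EGFP, WT and L122A RA libraries at 143, 113 and 76.2, against values from -84.2 (WT LIF) to 4.74 (EGFP no-LIF) for the others. EGFP no-LIF lay at -91.1 on the second component, which held 14.0% of the variance, and the next lowest library, EGFP LIF, at -21.4. The L122A no-LIF library lay beside the LIF libraries of the Nanog transfectants, at -80.4 on the first component against -84.2 for WT LIF and -74.7 for L122A LIF.

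**Figure D1:**
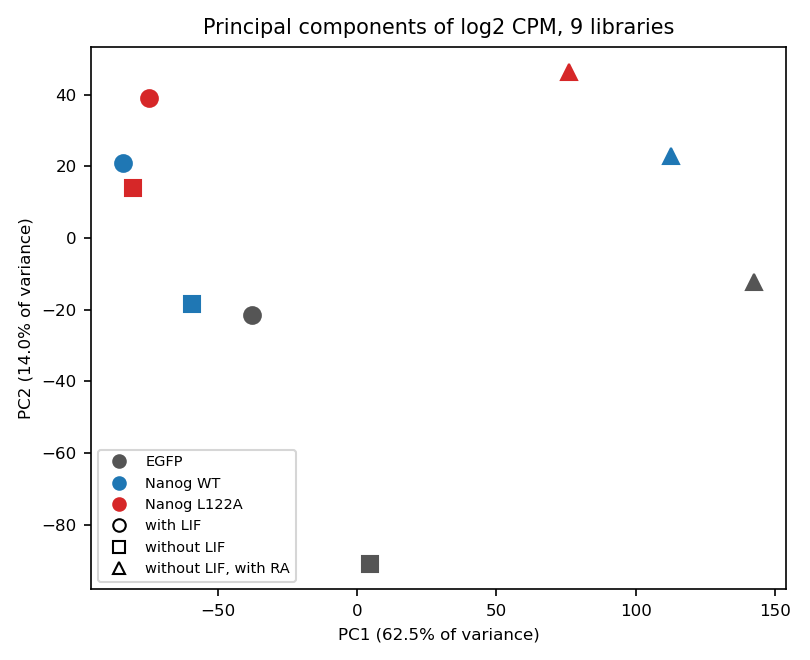
Scores of the 9 libraries on the first and second principal components of log2 CPM, with 62.5% and 14.0% of the variance on the axes; colour gives the transfectant, symbol the culture, and each point is 1 library. The RA libraries lie between 76.2 and 143 on the first component and EGFP no-LIF lies lowest on the second, at -91.1.

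Nanog (ENSMUSG00000012396, mm9 chromosome 6, 122657507 to 122664651), the transfected gene, was read first in every library. With LIF it stood at 385 CPM in EGFP, 223 in WT and 240 in L122A, and without LIF at 291, 168 and 130 CPM, so its counts were not higher in the Nanog transfectants in either culture. With RA it stood at 0.873 CPM in EGFP (28 counts), 195 in WT and 259 in L122A, which was 224-fold (95% Poisson interval 155 to 337) and 297-fold (205 to 447) above EGFP. The intervals cover counting error only. The labels do not say which species' Nanog was transfected or whether reads of the construct align to this gene, so these counts do not separate endogenous from transfected transcripts.

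The first comparison asked what LIF withdrawal changed across the 3 transfectants. Of the 10 genes called, 8 fell, among them 2 naive pluripotency genes and 2 LIF and STAT3 targets. Klf4, a naive pluripotency factor induced by LIF signalling (ENSMUSG00000003032, mm9 chromosome 4, 55540015 to 55545347), fell 10.2-fold (log2 fold change -3.35, SE 0.30, adjusted p = 0.016), and Bcl3, a target of the LIF-activated factor STAT3 (ENSMUSG00000053175, chromosome 7, 20393811 to 20408119), fell 10.7-fold (-3.43, SE 0.30, adjusted p = 0.016). Tbx3, a further naive factor, fell 4.47-fold and Stat3 itself 3.26-fold (adjusted p = 0.0342 and 0.0445). Hs3st3b1 and Cltb also fell, while the iron exporter gene Slc40a1 rose 11.1-fold. These 7 were among the 10 genes that passed the test of 13996, of which 2 rose.

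By list, 2 of 15 naive pluripotency genes fell over all genes tested and 4 adjusted over the list alone (median log2 fold change -1.66, camera adjusted p = 1.6e-07, adjusted p = 0.50 with an estimated correlation). Of 12 LIF and STAT3 targets, 2 fell over all genes and 6 adjusted over the list alone (median -1.24, camera adjusted p = 2.64e-06, adjusted p = 0.26 with an estimated correlation). The formative and primed epiblast list, genes of the post-implantation epiblast, stood higher as a set (median 1.63, camera adjusted p = 1.49e-04, adjusted p = 0.50 with an estimated correlation), with 0 of 12 called over all genes by edgeR and 5 higher adjusted over the list alone; its member Fgf5 had a log2 fold change of 5.04 (SE 1.25, adjusted p = 0.32). The 3 cleavage stage genes, which belong to near-identical families, had a median of -1.62 (camera adjusted p = 0.0235, adjusted p = 0.56 with an estimated correlation). No other list passed camera, and the p53 list had a median of 0.03 with a test pointing down. By directional fry the LIF and STAT3 list alone passed (adjusted p = 0.0253). The call count of 10 became 0 without WT LIF, WT no-LIF or L122A LIF, 1 without L122A no-LIF, 2 without EGFP LIF, EGFP no-LIF or WT RA, 18 without L122A RA and 44 without EGFP RA. DESeq2 called 278 genes, 157 higher and 121 lower, and edgeR with only the levels compared 48 higher and 42 lower, so the balance of 2 higher and 8 lower did not hold. Klf4 lost its call without WT LIF, WT no-LIF or L122A LIF and Bcl3 also without EGFP LIF or L122A no-LIF, whereas the others named lost theirs without any library except EGFP RA or L122A RA.

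The second question was what RA changed. RA switched on its own degradation enzymes and the anterior Hox genes in all 3 transfectants and brought most pluripotency transcripts down. The RA cultures also lacked LIF, so fold changes against the LIF cultures hold both changes. Cyp26a1 and Cyp26b1, the RA-degrading cytochromes P450, rose 771-fold and 686-fold over the LIF cultures (log2 9.59, SE 1.41, adjusted p = 0.0015, and 9.42, SE 0.88, adjusted p = 3.82e-04). Tbx2, a T-box factor (ENSMUSG00000000093, chromosome 11, 85646053 to 85655450), rose 1424-fold (log2 10.48, SE 0.80, adjusted p = 2.12e-04), and Hoxb5os, an antisense transcript of the Hoxb cluster (chromosome 11, 96152338 to 96168224), had the largest increase (log2 10.96, SE 0.68, adjusted p = 1.09e-04), although the strand of counting is not given and Hoxb6 overlaps it. Tdgf1, the Nodal co-receptor gene (ENSMUSG00000032494, chromosome 9, 110818342 to 110848571), fell 213-fold (log2 -7.74, SE 0.45, adjusted p = 9.66e-05), Tcl1 fell 333-fold and Otx2, an epiblast and forebrain factor, fell 176-fold.

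Against the LIF cultures, all 12 anterior Hox genes tested rose (median log2 6.10, camera adjusted p = 2.49e-06), as did 14 of 16 RA response genes, while Crabp1 fell (median 5.14, camera adjusted p = 5.65e-06), and 13 of 15 extraembryonic endoderm genes, with Amn falling (median 3.31, camera adjusted p = 1.09e-04). With an estimated correlation the adjusted p was 0.42 for the Hox and endoderm lists and 0.11 for the RA response list. In the endoderm list Foxa2 rose 83.7-fold and Pdgfra 33.8-fold. Of 15 general pluripotency genes 12 fell (median -3.24, camera adjusted p = 7.51e-05), including Fgf4, and of 15 naive genes 11 fell and 1, Tbx3, rose 5.16-fold (median -4.30, camera adjusted p = 3.96e-04; adjusted p = 0.42 for both lists with an estimated correlation). Nanog itself had a log2 fold change of -0.97 (SE 1.37, adjusted p = 0.58), as its level with RA depended on the transfectant. Of 10 fibroblast genes 8 rose (median 2.41, camera adjusted p = 0.0025), Col3a1 by 242-fold, and 12 of 15 cell cycle genes fell modestly, Pcna by 2.44-fold (median -0.85, camera adjusted p = 0.0012; adjusted p = 0.42 for both lists with an estimated correlation). Of 13 p53 targets 9 rose, among them Cdkn1a (4.32-fold), which blocks the cell cycle, and Bax fell (median 1.24, camera adjusted p = 0.0026, adjusted p = 0.42 with an estimated correlation). Counts adjusted over the list alone were 12 of 12 Hox, 14 higher and 1 lower RA response, 13 and 1 endoderm, 13 lower general, 12 lower and 1 higher naive, 8 higher fibroblast, 12 lower and 1 higher cell cycle, and 11 higher and 1 lower p53 genes. Without a filter on low counts, 3 general and 7 naive genes were called lower, and with limma on FPKM 5 cell cycle genes. By directional fry the adjusted p of the lists named so far for this comparison was between 1.62e-04 (RA response) and 0.0156 (naive).

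The remaining lists did not pass camera. By directional fry, Nodal and BMP (adjusted p = 0.0026), neural (0.0096), cleavage stage (0.0255) and mesoderm genes (0.0489) passed. Of 11 Nodal and BMP targets, 7 rose, with the BMP-responsive Msx2 (18.4-fold) and Smad6 (10.5-fold) in front, and 3 fell, among them the Nodal targets Lefty1 (10.5-fold) and Lefty2 (18.0-fold). Of 10 trophectoderm genes 3 rose, with Gata3 20.9-fold higher, and 2 fell. Of 10 neural genes 4 rose, including Nes at 11.5-fold, and 1 fell. Of 9 mesoderm genes 4 rose and 1 fell, of 11 germ cell genes 3 fell, and of 3 cleavage stage genes 2 fell. Of 12 LIF and STAT3 targets 3 rose, Stat3 2.26-fold among them, and 5 fell, and of 12 formative genes 2 rose, with Sox4 17.2-fold higher, and 2 fell. The counts that moved by over 1.5 times without 1 library were these. Without WT RA, 1 LIF and STAT3 target and 2 mesoderm genes rose and 1 Nodal and BMP target fell. Without the same library, 1 formative gene rose and 1 fell. Without WT LIF, 3 LIF and STAT3 targets, 1 Nodal and BMP target and 1 germ cell gene fell and 1 formative gene rose. Without EGFP LIF, 1 Nodal and BMP target, 1 formative gene and 2 mesoderm genes fell, and without EGFP no-LIF 1 formative gene rose and 2 neural genes fell. Without EGFP RA, 2 mesoderm and 2 neural genes fell. Without L122A LIF, 3 LIF and STAT3 targets fell and 5 trophectoderm genes and 1 formative gene rose, and without L122A RA 4 formative genes fell and 1 rose. The fall of 1 mesoderm gene was lost without WT or L122A LIF or RA, that of 1 neural gene also without EGFP LIF, and trophectoderm genes that fell were 1 without any library except EGFP no-LIF. Adjusted over the list alone the counts higher and lower were 7 and 3 (Nodal and BMP), 4 and 2 (trophectoderm), 4 and 2 (neural), 4 and 1 (mesoderm), 0 and 2 (germ cell), 0 and 2 (cleavage stage), 3 and 5 (LIF and STAT3) and 1 and 2 (formative).

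In all, 6751 genes passed the edgeR test with RA against LIF, 3423 higher and 3328 lower, and 4946 of them by at least 2-fold. Scaling by total counts in place of trimmed-mean factors gave 4503 higher and 1945 lower and put the median of all genes at 0.39, so the balance of higher against lower calls depends on the scaling. The count was 4488 without WT LIF and 4232 without WT RA. Cell cycle genes called lower were 4 with total-count scaling. Without WT RA they were 6, and without WT LIF, fibroblast genes called higher were 5. Amn and Crabp1 lost their calls without 1 library: Amn without any but L122A LIF, and Crabp1 without WT LIF, WT RA or any L122A library. Foxa2 lost its call without EGFP LIF, WT LIF, WT RA, L122A LIF or L122A RA, Lefty2 without EGFP LIF, WT LIF or WT RA, and Bax without WT RA. The log2 fold change of Foxa2 was 9.30 without EGFP LIF and 4.21 without WT RA.

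The RA cultures were also set against the cultures without LIF, as both lack LIF. Of the RA response genes 13 of 16 rose, as did all 12 Hox genes, 13 of 15 endoderm genes, with Gata6 100.4-fold and Lama1 60.2-fold higher, 10 of 13 p53 targets and 7 of 10 fibroblast genes, while 10 of 15 general pluripotency genes and 11 of 15 cell cycle genes fell (camera adjusted p between 3.65e-06 for Hox and 0.0044 for fibroblast genes; adjusted p = 0.10 for the RA response list and 0.51 for the others with an estimated correlation). Hoxc8 rose 734-fold (log2 9.52, SE 0.53, adjusted p = 8.46e-05) and Cyp26b1 341-fold. Among genes that LIF withdrawal had lowered, Tbx3 rose 23.1-fold (log2 4.53, SE 0.25, adjusted p = 8.46e-05), Stat3 7.37-fold, Bcl3 5.46-fold and Klf4 2.39-fold. Both comparisons use the no-LIF libraries, so picking genes that were low in them by itself favours a rise. Vrtn fell 822-fold, Otx2 810-fold (adjusted p = 6.11e-04) and Lef1 25.8-fold. Of 15 naive genes 8 fell and 2 rose (camera adjusted p = 0.0642), and of 12 formative genes 5 fell and 1 rose (0.0795). By directional fry these lists did not pass either (adjusted p = 0.28 and 0.10). The lists given before them did, with adjusted p between 1.92e-04 (RA response) and 0.0219 (general pluripotency). Directional fry was also passed by the Nodal and BMP (adjusted p = 0.008), neural (0.008) and LIF and STAT3 lists (0.0095). None of these passed camera, and each held called genes of both directions. Adjusted over the list alone, 13 RA response, 12 Hox, 13 endoderm, 11 p53 and 7 fibroblast genes were higher and 10 general, 11 cell cycle, 8 naive and 5 formative genes lower, beside 1 endoderm and 1 p53 gene lower and 1 cell cycle, 2 naive and 1 formative gene higher. edgeR called 6235 genes, 3168 higher and 3067 lower; with total-count scaling these were 4456 and 1679, the all-gene median was 0.43, and 4 cell cycle genes were called lower, as with limma on FPKM. Without a filter, 3 general, 2 naive and 3 formative genes were called lower. Without WT RA the count was 3615, and called lower were then 3 naive, 4 general and 7 cell cycle genes; without L122A no-LIF 2 naive genes, and without WT no-LIF 7 cell cycle genes, were called lower, and formative genes called lower were 3 without WT no-LIF or WT RA. The fold changes of the no-LIF and RA cultures against LIF share the LIF libraries. Their correlation across genes was 0.40 against 0.498 in simulations with no effect, and their covariance exceeded the simulated one by 0.312. Called in both were 2 higher and 4 lower genes, against 0.489 and 1.90 for independent lists and at most 1 and 0 in 20 simulations. The lists are not independent and the simulations hold no culture effect, so neither sets a baseline for this overlap.

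**Figure D2:**
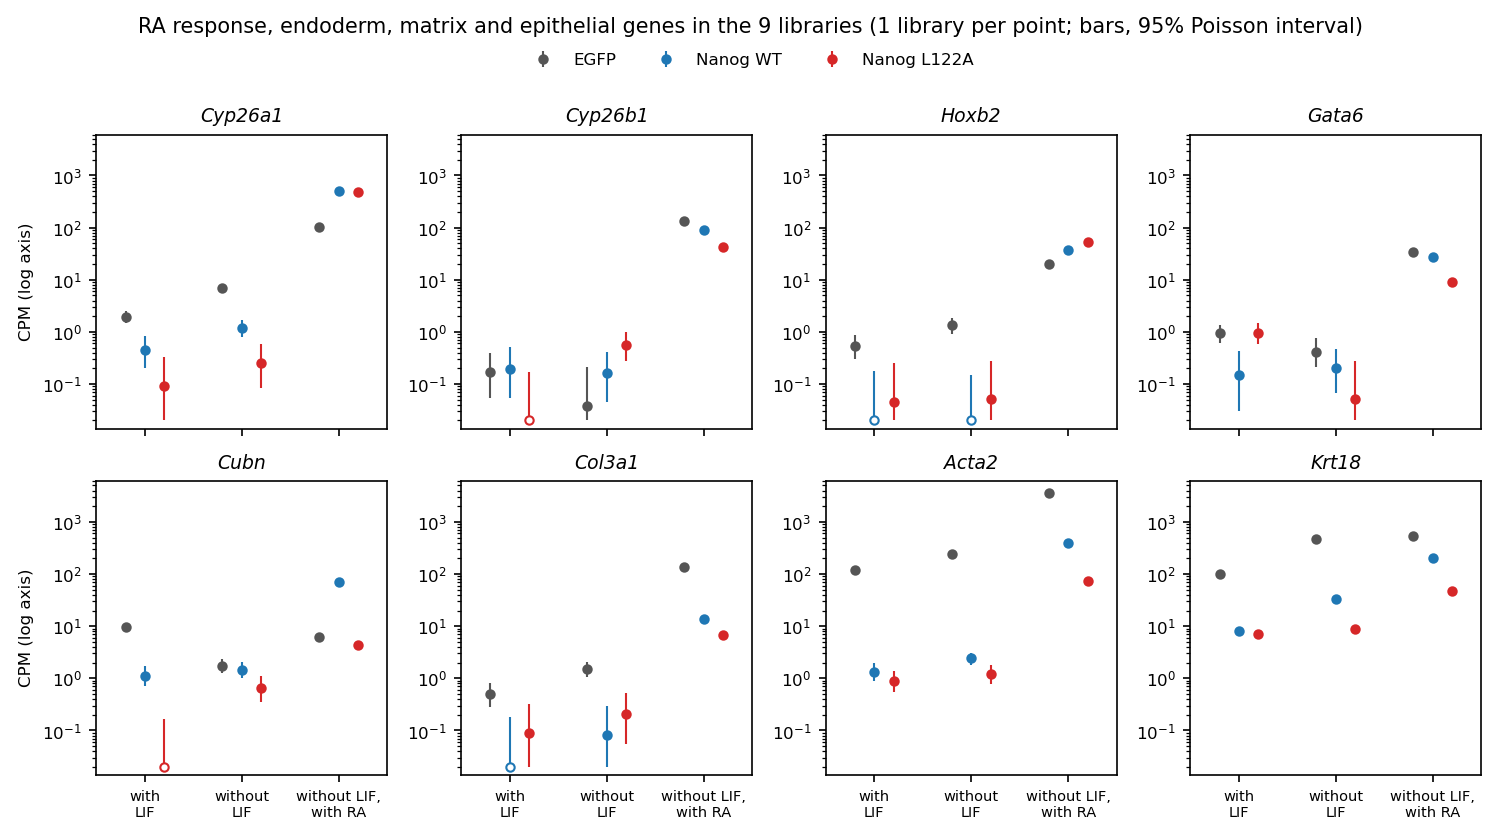
CPM on a log axis of 8 genes in the 9 libraries, by culture on the horizontal axis and by transfectant in colour; each point is 1 library, bars are exact 95% Poisson intervals and open symbols at the lower edge stand for 0 counts. Cyp26a1, Cyp26b1 and Hoxb2 are highest with RA in each transfectant, Cubn with RA stands at 70.1 CPM in WT against 6.11 in EGFP and 4.33 in L122A, and Acta2 stands at 3611, 393 and 73.1 CPM with RA in EGFP, WT and L122A.

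The third question was how the Nanog transfectants differed from EGFP over the 3 cultures. Of the 45 genes that edgeR called in WT cells, 40 were lower and 5 higher. No construct has independently transfected lines in the labels. A trait of the EGFP cells unrelated to Nanog would also repeat over the 3 cultures, and cannot be told apart from an effect of Nanog. Tnc, a matrix glycoprotein gene (ENSMUSG00000028364, chromosome 4, 63620819 to 63707850), fell 61.9-fold (log2 -5.95, SE 0.44, adjusted p = 0.0072). Cav1, which encodes the coat protein of caveolae, fell 62.6-fold (log2 -5.97, SE 0.65, adjusted p = 0.0244), the smooth muscle actin gene Acta2 fell 41.8-fold, and Rgs4 and Adam12 fell 42.7-fold and 28.1-fold. The size of these last falls depended on 1 library, as without WT RA the log2 fold changes of Rgs4 and Adam12 were -8.33 and -7.84. Wnt3, which acts in primitive streak formation, fell 7.51-fold and the collagen gene Col3a1 11.03-fold. The named increases were smaller: Sncg 6.64-fold (log2 2.73, SE 0.33, adjusted p = 0.0266), Aldoc 4.59-fold, Gm364 4.04-fold and Tceanc 2.85-fold.

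Lists lower in WT were fibroblast (1 of 10 fell and 6 adjusted over the list alone, median -2.67, camera adjusted p = 1.92e-05), trophectoderm (0 of 10 and 5, median -1.59, 4.05e-05), neural ectoderm (0 of 10 and 4, median -0.41, 0.0112), LIF and STAT3 targets (0 of 12 and 0, median -0.65, 0.0064) and mesoderm (1 of 9 and 1, median -1.28, 0.0259). Their adjusted p with an estimated correlation was 0.23 for fibroblast, trophectoderm and neural and 0.28 for the other 2. Lists higher were germ cell (0 of 11 called and 4 adjusted over the list alone, median 1.09, 2.41e-05), naive (0 of 15 and 1, median 0.98, 5.90e-04) and general pluripotency (0 of 15 and 0, median 0.78, 0.0028). With an estimated correlation these had adjusted p of 0.28, 0.44 and 0.51. Only the neural list had a directional fry adjusted p below 0.05, at 0.0303. The call count was 0 without WT no-LIF, 1 without WT LIF, 9 without EGFP no-LIF, 12 without WT RA, 127 without EGFP LIF and 148 without EGFP RA. DESeq2 called 609 genes. Tnc lost its call without WT no-LIF and Cav1 without any WT library; Sncg and Gm364 lost theirs without EGFP no-LIF or any WT library, and the others named in at least those cases except that Acta2 kept its call without WT RA.

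In L122A cells these genes were also lower than in EGFP. Rgs4 fell 163-fold (ENSMUSG00000038530, chromosome 1, 171671608 to 171677773; log2 -7.35, SE 0.74, adjusted p = 0.0067), Cav1 141-fold (log2 -7.14, SE 0.72, adjusted p = 0.0067), Acta2 129-fold (log2 -7.01, SE 0.75, adjusted p = 0.0074), Tnc 95.4-fold (log2 -6.58, SE 0.47, adjusted p = 0.0029) and the protocadherin gene Pcdh7 91.4-fold. Wnt3 fell 14.4-fold, and the simple epithelial keratin genes Krt18 and Krt8 21.6-fold and 15.8-fold. The log2 fold change of Krt8 was -2.86 without EGFP no-LIF and -4.42 without EGFP LIF. Among the naive pluripotency genes Klf5 and Tbx3 rose by log2 1.71 and 1.32 (adjusted p = 0.0185 and 0.0242), and the germ cell gene Dazl rose 6.18-fold. Sncg (13.8-fold), Gm364 (12.8-fold), Mdga1 (17.2-fold), A2m (12.6-fold) and 2210409E12Rik (22.4-fold) had the largest increases. The log2 fold change of 2210409E12Rik was 3.61 without L122A no-LIF and 5.09 without EGFP LIF. edgeR called 403 genes, 125 higher and 278 lower; with total-count scaling it called 253, of which 20.9% were higher against 31.0%.

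The naive list was higher in L122A (2 of 15 rose, 4 adjusted over the list alone, median 1.45, camera adjusted p = 5.47e-05), with general pluripotency (0 of 15 and 0, median 1.28, 0.0015), germ cell (1 of 11 and 2, median 0.77, 0.0037) and cell cycle genes (0 of 15 and 0, median 0.35, 0.0035). Their adjusted p with an estimated correlation was 0.37 for the naive list and 0.43 for the others. Lower were fibroblast (4 of 10 fell and 4 adjusted over the list alone, Col1a2 34.4-fold and Dcn 28.1-fold, median -2.13, 6.77e-04), trophectoderm (4 of 10 and 4, median -1.51, 9.86e-04), extraembryonic endoderm (1 of 15 and 6, median -1.65, 0.0033), LIF and STAT3 targets (0 of 12 and 2, median -0.57, 0.0158), neural (3 of 10 and 4, median -0.66, 0.0262) and p53 genes (0 of 13 and 0, median -0.39, 0.0482). With an estimated correlation their adjusted p was 0.34 (fibroblast, trophectoderm, neural, LIF and STAT3), 0.43 (endoderm) and 0.46 (p53). Only the neural list passed directional fry (adjusted p = 0.0271). The count of 403 was 24 without L122A no-LIF, 123 without EGFP no-LIF, 128 without L122A RA, 139 without WT LIF, 218 without WT no-LIF and 246 without WT RA. DESeq2 called 1438. Sncg, Gm364, Rgs4, Cav1 and Tnc kept their calls without any 1 library, Acta2, Pcdh7 and Wnt3 lost theirs without L122A no-LIF, and without that library naive, trophectoderm, neural and fibroblast calls were each 0. Without L122A RA they were 1, 0, 0 and 1, and Krt18, Col1a2 and Dcn lost their calls without either of these libraries. Without EGFP LIF 4 naive and 2 trophectoderm genes passed, without EGFP no-LIF 1 naive, 1 trophectoderm and 1 neural gene, without WT LIF the same numbers, and without WT no-LIF 1 trophectoderm gene. Endoderm genes that fell were 4 without EGFP RA, 2 without WT RA and 0 without EGFP no-LIF, WT no-LIF, L122A no-LIF or L122A RA. Germ cell genes that rose were 3 without EGFP LIF and 0 without any other library except EGFP RA and L122A LIF. Klf5 lost its call without EGFP no-LIF or L122A no-LIF and Tbx3 without WT LIF or any L122A library. The calls of 2210409E12Rik, Mdga1, A2m, Krt8, Dazl and Lamb1 were each lost without any of at least 5 libraries.

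The fold changes of the Nanog transfectants against EGFP share the EGFP libraries, which alone gives a correlation across genes of 0.498 in simulations with no effect. The observed correlation was 0.834, and the covariance was 0.549 against 0.103 simulated, a difference of 0.446. Of the called genes 3 were higher and 40 lower in both, against 0.0447 and 0.795 for independent lists and at most 2 and 0 in 20 simulations of unchanged groups. The 3 control libraries are too few to be divided between the comparisons, so the part of the excess that comes from sharing them was not measured.

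L122A against WT gave 0 calls with edgeR, 614 genes at an unadjusted p below 0.05 where chance gives 699.8, and 51 calls with DESeq2. The extraembryonic endoderm list was lower in L122A (0 of 15 called, 1 lower adjusted over the list alone, median -0.87, camera adjusted p = 5.25e-04), and the naive (0 of 15 and 1 higher, median 0.56, 0.007), cleavage stage (0 of 3 and 2 higher, median 1.98, 0.0071) and cell cycle lists (0 of 15 and 0, median 0.23, 0.0142) were higher, all with adjusted p = 0.99 with an estimated correlation. Lamb1, a laminin gene of the endoderm list, had a log2 fold change of -1.05 (SE 0.22, adjusted p = 0.71), and Klf5 of 1.06 (SE 0.26, adjusted p = 0.73). Median and test differed in sign for the Nodal and BMP, Hox, RA response and fibroblast lists, none of which passed camera.

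The fourth question was whether the response to a culture differed between the Nanog transfectants, taken as 1 class, and EGFP. On LIF withdrawal the naive pluripotency list stood lower in each transfectant, by a median log2 ratio of single libraries of -3.39 in EGFP, -0.84 in WT and -0.74 in L122A, with 13, 6 and 4 of 15 members at least 2-fold lower. In EGFP cells, Esrrb went from 115 CPM with LIF to 3.48 without, Zfp42 from 621 to 59.3 and Nr0b1 stood at 3.13 without LIF. In WT cells without LIF these genes stood at 75.2, 600.5 and 62.7 CPM, and in L122A cells at 114, 1121 and 196.5 CPM. The naive list had a median difference of responses of 2.92 (log2; camera adjusted p = 2.27e-04, adjusted p = 0.45 with an estimated correlation). Klf2 had the smallest p in it (log2 3.96, SE 0.67, adjusted p = 0.33). The difference of responses was also positive for general pluripotency (median 1.16, camera adjusted p = 0.0063), Hox (1.23, 0.0079) and germ cell genes (1.265, 2.27e-04). It was negative for mesoderm genes (-1.85, 0.0085) and p53 targets (-0.72, 0.0028). The adjusted p of these lists with an estimated correlation was between 0.29 and 0.61. Median and test differed in sign for the Nodal and BMP, RA response and neural lists, none of which passed. The Hox median was 1.075 with 2 members set at a floor of 3 counts per group. Hox genes stood below EGFP in both cultures. Their median log2 ratio without LIF was -1.08 in WT and -1.40 in L122A, or -1.08 and -1.10 with the floor. With LIF it was -3.08 and -2.53, or -1.98 and -2.43 with the floor. No gene passed the test in edgeR (1117 at an unadjusted p below 0.05), DESeq2 called 120, and 24, 22 and 1 passed in edgeR without WT RA, L122A RA and EGFP RA. Adjusted over the list alone, 2 naive, 2 general, 1 Hox and 1 germ cell gene were higher and 3 p53 genes lower.

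With RA, Nanog was the 1 gene whose response was called different (log2 difference of responses 8.75, SE 0.50, adjusted p = 4.98e-04). Pou5f1, a core pluripotency factor, stood at 0.468 CPM in EGFP RA (15 counts), 9.24 in WT RA and 70.2 in L122A RA; Esrrb at 0.156 (5 counts), 5.76 and 138; Zfp42 at 6.20, 24.4 and 149; and Sall4 at 14.1, 104 and 119 CPM. Tdgf1, by contrast, stood at 2.74, 8.74 and 9.72 CPM, against 1062, 2046 and 1260 CPM with LIF. The general pluripotency list had a median of 4.12 (camera adjusted p = 9.31e-10, 9 of 15 higher adjusted over the list alone) and the naive list of 3.99 (2.45e-05, 2 of 15), or 3.14 with 3 members set at a floor of 3 counts. The adjusted p was 0.33 for both with an estimated correlation. Nanog, whose counts may include the construct, is a member of the naive list and the only one called over all genes. Against EGFP the naive median went from 0.10 with LIF to 0.61 with RA in WT. In L122A it went from 0.29 to 3.10, or to 2.59 with the floor. Hox genes had a median of 4.87, or 4.58 with 2 members at the floor (camera adjusted p = 1.92e-10, adjusted p = 0.0902 with an estimated correlation, 10 of 12). By directional fry Hox genes alone passed (adjusted p = 4.69e-04). Their median log2 ratio to EGFP was -3.08 in WT and -2.53 in L122A with LIF, or -1.98 and -2.43 with members at 0 set at the floor, and 0.84 and 0.74 with RA. Formative (1.77, 0.0029; 1 of 12), extraembryonic endoderm (1.95, 9.37e-04; 2 of 15), germ cell (1.72, 7.52e-04; 3 of 11) and cell cycle genes (0.72, 0.0042; 0 of 15) were higher, and fibroblast (-0.61, 0.0208; 1 of 10 lower) and p53 genes (-0.89, 3.90e-04; 2 of 13 lower) lower. With an estimated correlation the adjusted p of these 6 lists was between 0.25 and 0.47. The endoderm list stood at median log2 ratios to EGFP of -1.62 in WT and -0.84 in L122A with LIF, or -0.98 and -0.81 with members at 0 set at the floor, and of 0.71 and -1.03 with RA. DESeq2 called 261 genes, and edgeR 166 without WT RA, 29 without L122A RA and 7 without WT no-LIF or L122A no-LIF. The spread in these tests is the difference between WT and L122A, and the lone EGFP library of each culture is assumed to vary like that.

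**Figure D3:**
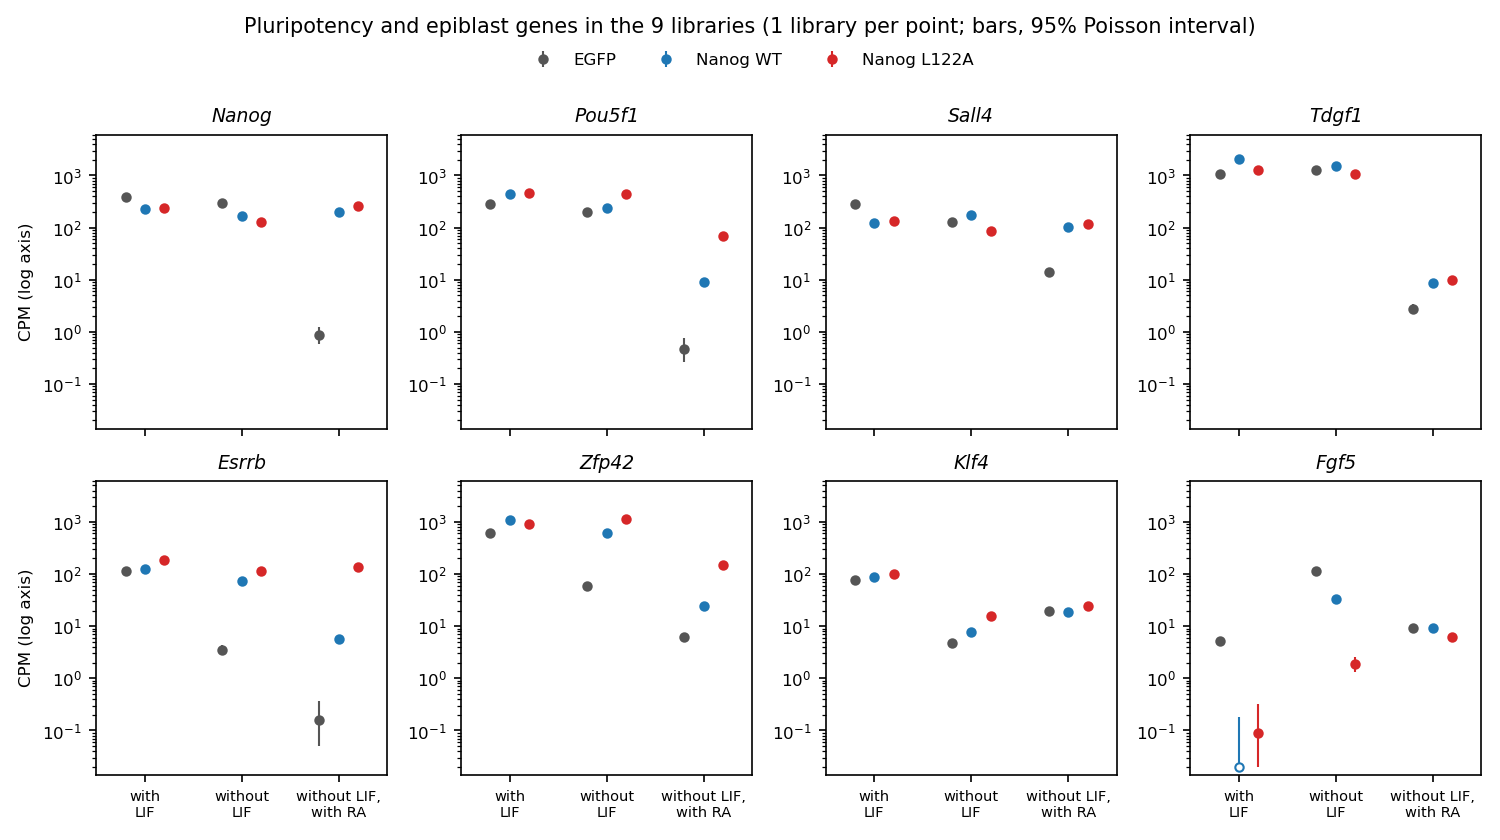
CPM on a log axis of 8 pluripotency and epiblast genes in the 9 libraries, by culture on the horizontal axis and by transfectant in colour; each point is 1 library, bars are exact 95% Poisson intervals and the open symbol at the lower edge stands for 0 counts. Nanog with RA stands at 0.873 CPM in EGFP and at 195 and 259 CPM in WT and L122A, Esrrb at 0.156, 5.76 and 138 CPM, and Tdgf1 below 10 CPM in all 3 transfectants.

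Within a culture, 2 libraries can be compared only as libraries, with no test. Counting genes at least 2-fold apart with at least 5 CPM in the higher library, WT and EGFP differed at 1023 genes with LIF, 1622 without LIF and 1139 with RA, L122A and EGFP at 954, 2037 and 1988, and L122A and WT at 347, 802 and 732. Both ratios to EGFP in a culture use the same EGFP library, so some agreement in direction arises without any effect. With LIF, 1 gene moved in opposite directions, and 196 genes were higher and 315 lower in both Nanog libraries than in EGFP. Among those, Acta2 stood at 120 CPM in EGFP, 1.33 in WT and 0.904 in L122A, and the interferon-inducible guanylate-binding protein genes Gbp1 and Gbp2 stood at 35.9 and 36.2 CPM in EGFP against 0.246 and 0.591 in WT and 0.316 and 0.633 in L122A; Myl4, a myosin light chain gene, stood at 2.61, 27.9 and 43.1 CPM. The naive list had a median log2 ratio to EGFP of 0.10 in WT and 0.29 in L122A (percentiles 73.1 and 97.5 of 10000 random lists matched on expression).

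Without LIF, 497 genes were higher and 638 lower in both, and 4 moved in opposite directions. The naive list had medians of 2.67 in WT and 2.09 in L122A, both above all random lists. EGFP cells without LIF held transcripts of primitive streak genes: T at 106 CPM, Fgf8 at 20.1 and Mixl1 at 18.3, against 0.164, 0.695 and 1.64 CPM in WT and 0, 0 and 0.963 CPM in L122A, where a count of 0 allows up to 0.187 CPM at the upper end of its interval. Krt18 stood at 475, 33.2 and 8.72 CPM, and the endothelin gene Edn1 and the chemokine gene Cxcl11 at 39.1 and 30.1 CPM in EGFP against 0 (upper limit 0.151) and 0.327 in WT and 0.254 and 0 in L122A. The Nanog libraries differed from each other in the formative list, whose median ratio to EGFP was 0.78 in WT and -0.94 in L122A (percentiles 99.9 and 0.08), and -1.26 in L122A against WT (below all random lists). Otx2 stood at 31.4, 139 and 9.89 CPM in EGFP, WT and L122A, Dnmt3b at 223, 426 and 98.3, Dnmt3a at 56.1, 362 and 111, and Fgf5 at 112, 33.7 and 1.88. The LIF target Socs3 went from 18.0 CPM with LIF to 4.09 without in EGFP, from 19.7 to 0.654 in WT and from 25.2 to 0.203 in L122A.

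With RA, 294 genes were higher and 606 lower in both, and 4 moved in opposite directions. The naive and general pluripotency lists had median ratios to EGFP of 0.61 and 1.74 in WT and 3.10 and 3.12 in L122A (2.59 for the naive list in L122A with 3 members at the floor), and L122A lay above WT by a median of 1.73 and 1.11. The extraembryonic endoderm list separated the Nanog libraries the other way, with 0.71 in WT and -1.03 in L122A (percentiles 99.9 and 0.01) and 11 of 15 genes at least 2-fold lower in L122A than in WT. Cubn, an endocytic receptor gene of visceral endoderm, stood at 6.11, 70.1 and 4.33 CPM in EGFP, WT and L122A, Lama1 at 20.6, 210 and 67.5 CPM and Sparc at 3142, 1596 and 656 CPM. The fibroblast list lay at -2.21 in WT and -2.97 in L122A, with Col3a1 at 139, 13.6 and 6.91 CPM.

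**Figure D4:**
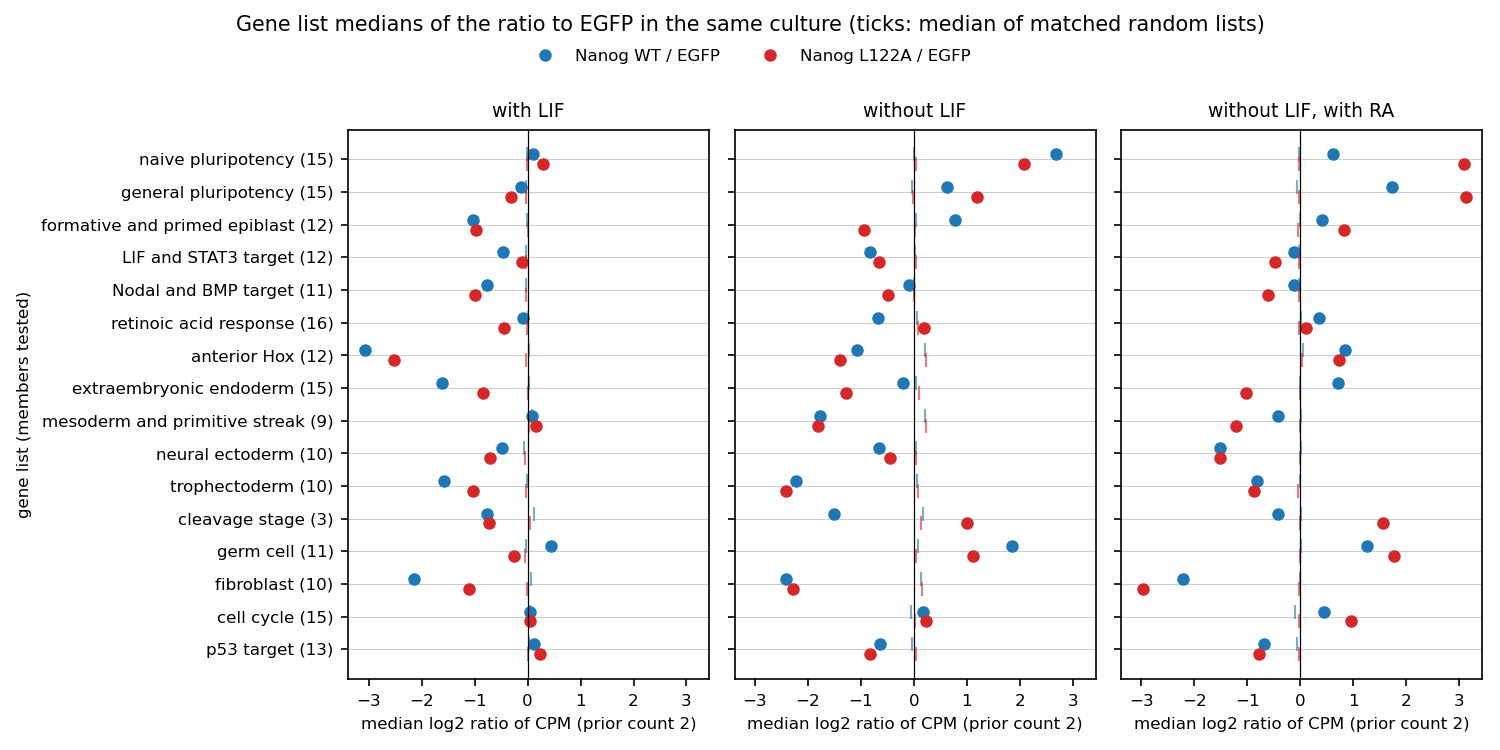
Median log2 ratio of CPM to the EGFP library of the same culture (horizontal axis, prior count 2) of the 16 gene lists (vertical axis, members tested in brackets), 1 panel per culture; points are WT in blue and L122A in red, and ticks are the medians of matched random lists. The naive list lies at 0.10 and 0.29 with LIF, 2.67 and 2.09 without LIF, and 0.61 and 3.10 with RA in WT and L122A.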

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

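The tests of explanations given here were all chosen after the results had been seen, while the test of the difference between responses had been planned. That test set the response of the Nanog transfectants to a culture against the response of EGFP cells, and it singled out the results given here as log2 differences of responses.

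With RA, Nanog itself differed by 8.75. The median difference was 3.99 for naive pluripotency, 4.12 for general pluripotency, 1.77 for formative epiblast, 4.87 for Hox, 1.95 for extraembryonic endoderm, 1.72 for germ cell, 0.72 for cell cycle, -0.61 for fibroblast and -0.89 for p53 target genes. Each value pools WT and L122A. The naive list went from a median log2 ratio to EGFP of 0.10 with LIF to 0.61 with RA in WT. In L122A it went from 0.29 to 3.10, or to 2.59 with members at 0 set at the floor of 3 counts. The general list went from -0.12 to 1.74 in WT and from -0.32 to 3.12 in L122A. The Hox value rests in part on genes near the floor: with LIF the list stood at a median log2 ratio to EGFP of -3.08 in WT and -2.53 in L122A, or -1.98 and -2.43 with 6 and 2 of 12 members at 0 set at the floor of 3 counts, against 0.84 and 0.74 with RA. The endoderm list stood at -1.62 and -0.84 with LIF, or -0.98 and -0.81 with the floor, against 0.71 and -1.03 with RA, so that in L122A it lay below EGFP in both cultures. On LIF withdrawal the median difference was 2.92 for naive pluripotency, 1.16 for general pluripotency, 1.23 for Hox, 1.265 for germ cell, -1.85 for mesoderm and -0.72 for p53 target genes. The Hox list stood below EGFP without LIF too, at a median log2 ratio of -1.08 in WT and -1.40 in L122A. None of these list results had a camera adjusted p below 0.05 with an estimated correlation, the smallest being 0.0902 for Hox with RA. By directional fry, Hox with RA passed (adjusted p = 4.69e-04), and the smallest fry adjusted p of the others was 0.0616.

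Pluripotency transcripts were lost less completely with RA in the Nanog transfectants than in EGFP, with median log2 ratios to LIF of -6.63, -4.44 and -2.04 for the naive and -6.10, -3.04 and -1.46 for the general list in EGFP, WT and L122A. A constant share of cells as in the LIF culture would keep at 1 level 71 transcripts picked for a fall of at least 16-fold in EGFP RA. The level kept had a median of 6.02% in WT and 21.6% in L122A. It differed by 27.4-fold in WT and 9.29-fold in L122A between its 10th and 90th percentiles. The level that EGFP itself kept was not set beside these. In WT, where the level kept was low, transcripts of differentiated cells could spread it, so the test cannot decide for WT. A culture that hardly met RA would show less induction. Instead, the 21 RA response and Hox genes induced at least 4-fold in EGFP stood at a median log2 ratio to EGFP of 0.51 in WT and 0.43 in L122A. The whole RA response list stood at 0.35 and 0.10. Reads of the construct would raise Nanog alone, whereas 23 of 29 other members of the pluripotency lists were at least 2-fold higher in L122A, and in WT 6 of 15 naive members, with Nanog among the 15, and 10 of 15 general members. For Nanog itself, at 259 CPM in L122A RA, transfected and endogenous transcripts cannot be told apart, as the labels do not give the construct's sequence. Partly differentiated or mixed cells stay open, and an action of Nanog in these cells may be the cause but was found on the same data.

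The formative epiblast list stood lower in L122A no-LIF, at a median log2 ratio of -0.94 to EGFP no-LIF and -1.26 to WT no-LIF. Not every member was lower, as Dnmt3a stood above EGFP. The list stood above L122A LIF by a median log2 ratio of 1.04 (4 of 12 at least 2-fold higher, 0 lower). The L122A no-LIF library had its closest match in WT LIF (chi-square per degree of freedom 23.5). If it were a culture with LIF, LIF and STAT3 targets would stand as in L122A LIF, whereas their median log2 ratio to it was -1.28. If it had been exchanged with WT LIF, these targets would be low in the library called WT LIF, whereas they stood above WT no-LIF by a median of 1.12. A shorter time without LIF was not tested, and a difference between L122A and WT Nanog may account for the pattern but rests on 1 library.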

How the results depend on the processing

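Total-count scaling, the omission of ribosomal RNA and mitochondrial genes, and the splits of the libraries were chosen after the data had been seen. No called fold change of a named gene changed sign under the alternatives compared gene by gene, which leave out the model without the second factor. Of those not called, 2 did with total counts and 11 on leaving out a library. On LIF withdrawal the balance of calls turned, from 2 higher and 8 lower to 157 and 121 with DESeq2 and 48 and 42 with only the levels compared, and for the difference with RA from 1 and 0 to 9 and 11 with limma on FPKM. RLE factors and the omission of ribosomal RNA and mitochondrial genes kept all 8 counts of called genes within 1.5 times. Without a filter, 37 genes were called on LIF withdrawal, 138 in WT against EGFP, 1 in L122A against WT, 403 for the difference of responses without LIF and 684 with RA; 384 and 652 of the latter pass the filter, and the cause was not tested. DESeq2 called 278 on LIF withdrawal, 609 in WT and 1438 in L122A against EGFP, 51 in L122A against WT, and 120 and 261 for the differences of responses. With only the levels compared, and so fewer libraries, the counts in the same order were 90, 99, 82, 4, 81 and 6. limma on FPKM called 4 on LIF withdrawal, 19 and 217 in WT and L122A against EGFP and 20 for the difference with RA. Without the second factor the counts on LIF withdrawal and against EGFP were 0, 0 and 0, and with total-count scaling 2, 22 and 253. For all these changes the cause was not tested.

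Leaving out 1 library gave between 0 (without WT LIF, WT no-LIF or L122A LIF) and 44 (EGFP RA) calls on LIF withdrawal, 4232 (WT RA) and 6680 (EGFP no-LIF) for RA against LIF, 3615 (WT RA) and 6314 (EGFP LIF) for RA against no LIF, 0 (WT no-LIF) and 148 (EGFP RA) for WT against EGFP, 24 (L122A no-LIF) and 558 (EGFP LIF) for L122A against EGFP, 0 and 24 (WT RA) for the difference without LIF, and 1 and 166 (WT RA) for the difference with RA. L122A against WT had 0 edgeR calls in each case. The differences of responses cannot be estimated without an EGFP library they use. Among log2 fold changes of named genes, the call was lost in 1 case with RLE factors, 39 with FPKM, 24 without a filter, 19 with only the levels compared, 25 with total counts and 264 on leaving out a library, and gained in 45 with DESeq2, 2 with FPKM, 29 without a filter, 10 with only the levels compared and 28 on leaving out a library. Of the called members of lists 172 counts moved and 402 kept within 1.5 times on leaving out a library. Of the 2-fold counts of library pairs, 11 moved by over 1.5 times with a minimum of 1 CPM.

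The 6 libraries of a comparison allow 10 splits into 3 and 3, too few for a share under 0.05 as the real split is 1 of them. Real and highest other counts were 10 and 0 (LIF withdrawal), 6751 and 0, 6235 and 0 (RA), 45 and 0 (WT), and 403 and 1 (L122A against EGFP), each reached by 1 of the 10 splits, and 0 and 0 (L122A against WT), reached by all 10. In the other splits any real difference goes into the spread, which by itself favours low counts, so these counts do not measure chance. With 1 library per combination, at most 22.4% of 2-fold changes were recovered in simulated data with 200 changed genes. Recovery was not measured with more changed genes. In RA against LIF, 4946 of the 6751 called genes reached 2-fold, so smaller changes were called there too. The simulated share therefore does not describe that comparison.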

Other observations

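The lists of ribosomal protein genes and of YAP and TEAD targets, and all tests given here, were chosen after the results had been seen.

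Ribosomal protein genes stood lower with RA in all 3 transfectants. Their share of counts was 6.53%, 7.32% and 7.05% in the EGFP, WT and L122A RA libraries and between 12.1% and 14.9% in the others. Of 77 such genes 76 fell in edgeR against LIF (median log2 -1.34, camera p = 0.107 with an estimated correlation) and 75 against no LIF (median -1.44, p = 0.0917). With total-count scaling, which put the median of all genes at 0.39, 69 fell, with a median of -0.95, or -1.34 relative to all genes.

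Transcripts of the actin gene Acta2, the matrix gene Tnc and Cav1 were lower in the Nanog transfectants than in EGFP. Whether this is a trait of the EGFP cells or an effect of Nanog cannot be told, as the labels give no independently transfected lines. A candidate explanation is a lower output of YAP and TEAD, transcription regulators that respond to cell spreading, which would lower a list of their targets. The median log2 fold change of the 17 targets tested was -1.40 in WT and -1.51 in L122A, with 17 and 14 lower, of which 2 and 5 passed the test in edgeR (camera p = 0.0059 and 0.0137 with an estimated correlation). Fibroblasts in the EGFP cultures would bring collagen transcripts with Acta2; the CPM of Col1a1, Col1a2 and Col3a1 together was 0.101 of that of Acta2 (0.209 with LIF, 0.0854 without), and with no fibroblast library to set this against the 2 cannot be told apart. The same targets also stood higher with RA, where 13 of 17 rose against LIF and 13 against no LIF (median 2.35 and 2.27, camera p = 0.0261 and 0.0328 with an estimated correlation), so differentiated cells in the EGFP cultures stay open as an explanation, and protein activity was not measured.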
